A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

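RNA of Saccharomyces cerevisiae strains labelled as lacking a transcription factor gene (MET28, MET31, MET32 or CBF1) was set against wild-type RNA on 2-colour arrays. Per the labels' protocols, cultures were grown in YNB, a defined medium, at 30 °C to an optical density (OD600) of 0.8 to 1.0, total RNA was taken with hot phenol, and Cy3 or Cy5 was built directly into first-strand cDNA. The labels state at least 2 biological samples per strain, but each strain has 1 deposited column. The second channel is labelled wild type for met31 and met32 and wild type with methionine ("wt+met") for met28 and cbf1, so the kind of reference changes with the strain.

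The deposited table holds 1 signed value per open reading frame (ORF) and strain for 6260 ORFs, with at most 3 decimals. These were taken to be log ratios of the 2 channels. The log base, the centring, the background correction, the treatment of dye swaps and the averaging of biological samples are not given in the sources used here, and neither are channel intensities. The array medians as deposited were 0 on the met28, met31 and met32 arrays and -0.013 on the cbf1 array. The labels give the dyes as "Cy3 or Cy5" on each sample, which leaves the direction of the ratio open. Deletion strain over wild type was taken as the likely direction because MET28, MET31 and CBF1 had among the lowest values on their own arrays. For the met32 array the direction is not settled, so its list calls, the list differences picked out and its correlations are also given with the sign turned. Its single genes and runs of genes are given as deposited only. Values are printed as deposited.

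An exact 0 was listed 1018 times on the met28 array, 367 times on met31, 378 times on met32 and 877 times on cbf1. Each of the values next to 0 (up to 0.006 away, in steps of 0.001) occurred on average 27.8, 51.0, 43.9 and 19.4 times. Most zeros therefore cannot be ordinary measurements, and an exact 0 was treated as not measured. This left 5242, 5893, 5882 and 5383 measured ORFs, of which 4661 were measured on all 4 arrays. Gene symbols came from a RefSeq gene table of assembly R64, used for names and gene order only, which lists 5774 of the 6260 ORFs. The other 486 kept their systematic names.

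With 1 column per strain there is no replicate check and no residual spread, so no p-value or standard error could be given, and depth cannot be stated. The number of arrays limits the precision. As set before the data were examined for the case that the log base stays unknown, genes were described by size: those in the highest or lowest 2.5% of the measured values of an array, called its tails. The choice of 25 gene lists, the rule for named genes and most alternatives were also fixed before the data were examined. For each list and array, the median over measured members was placed among the medians of 10000 random lists of the same size from that array. A list is called apart when its median lay outside the central 95% of those medians. Without intensities, random lists could not be matched on expression, and the percentile describes these arrays only, since genes are not replicates. The ribosomal protein list was set by a rule on symbols and also holds RPP1, a gene of RNase P. Of the 100 medians, 5 would be apart by chance if the members of each list varied independently. Genes of a pathway can vary together on 1 array, so more may be apart without an effect of a deletion. Named genes are the deleted gene and other sulfur regulators, the 10 highest and 10 lowest genes with their own symbol on each array, up to 4 members of each list with the largest absolute values, and the 5 largest differences each way between arrays of a pair.

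Arrays with the same reference label were compared as pairs, met28 with cbf1 and met31 with met32, by Pearson and Spearman correlation across genes and by the overlap of tails beside the overlap of independent lists. What a shared wild-type RNA alone could give was simulated 100 times for unchanged strains. Values were drawn from normal distributions, with all spread assigned to the RNA samples, equally to wild type and strain. Means over the runs are given. The list placement was tested on simulated arrays with shuffled real values. Shuffling removes any joint variation of a list's members, and only upward shifts were tried. With no shift, 1.5% to 4.5% of lists of 7, 10 or 30 genes were called high and 2% to 4% were called low. With a shift of 0.05 the share called high was 16.5% to 100%, with 0.1 it was 53% to 100%, and with 0.2 it was 96% to 100%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

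Alternatives were other thresholds, median centring, arrays set to a common robust SD, list means, genes measured on all 4 arrays, and lists without the deleted genes, their neighbours and strain markers. The thresholds of 1.5-fold and 3-fold, the centring and the common SD were planned, and reading them on a log10 scale was chosen after the data were seen. The 2-fold counts for values read as log10, log2 or natural logarithms and zeros counted as values were added after the data were seen, and so was the ribosomal protein list without RPP1. Averaging of several probes per gene was not needed, since each ORF has 1 row. The planned search of promoters for Cbf1 and Met31/Met32 sites was not run, because no genome sequence was used here.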

Results

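Transcript levels were profiled in 4 yeast strains, each labelled as a deletion of a factor of the Met4-dependent sulfur regulatory system. Cbf1 binds DNA and recruits the activator Met4, Met28 is a cofactor that strengthens the binding of such complexes, and Met31 and Met32 are paralogous zinc-finger proteins that also recruit it. Each strain was set against wild type on a 2-colour array, and for met28 and cbf1 only, that wild type is labelled with methionine ("wt+met"). Each strain has 1 column of values for 6260 ORFs, so n = 1 throughout and differences have no replicate check. On the met28, met31, met32 and cbf1 arrays, 5242, 5893, 5882 and 5383 ORFs were measured. The measured values had robust SDs of 0.0778, 0.0519, 0.0608 and 0.110 in the deposited log ratio units.

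The deleted gene was examined first. MET28 was the lowest of all measured ORFs on the met28 array, at -1.3, and CBF1 was the fourth lowest on the cbf1 array, at -0.995. MET31 was the fifth lowest on the met31 array, at -0.320. If the values are log10 ratios, these are levels 19.7-fold, 9.89-fold and 2.09-fold below the reference channel. If they are log2 ratios, the levels are 2.45-fold, 1.99-fold and 1.25-fold below it. MET32 was at 0.012 on the array labelled met32, within a range of -0.066 to 0.027 over the 4 arrays, so that array gave no sign of the deletion. Among the other regulators, MET31 was at 0.598 on the met28 array, in its highest 2.5%, and MET28 was at 0.244 on the cbf1 array, also in the highest 2.5%. MET4, the activator gene itself, was listed at 0 on the met28, met31 and cbf1 arrays and at -0.001 on the met32 array. MET30, which encodes the ubiquitin ligase subunit that restrains Met4, lay between -0.128 and 0.099 on the 4 arrays, and GCN4 between -0.047 and 0.005.

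In the strain without MET28, genes that take up and reduce sulfate were low, and genes that import sulfur amino acids or use other sulfur sources were high. Of 9 measured genes of sulfate uptake and assimilation, 7 were in the lowest 2.5% and 0 in the highest, with a median of -0.362 that was below all 10000 random lists. They included the sulfate permease genes SUL2 (-0.801) and SUL1 (-0.745), MET16 (-0.576), which encodes the reductase of activated sulfate, and MET5 (-0.411), a sulfite reductase subunit gene. Of 7 measured genes of sulfur amino acid transport, 6 were in the highest 2.5%, with a median of 0.591 above all 10000 random lists. AGP3, an amino acid permease gene, was at 1.018, the methionine permease gene MUP1 at 0.933, the S-methylmethionine permease gene MMP1 at 0.919 and the cysteine transporter gene YCT1 at 0.591. Of 11 measured genes for alternative sulfur sources and sulfur sparing, 8 were in the highest 2.5%, with a median of 0.649. JLP1, a sulfonate dioxygenase gene, was at 0.977, SEO1, a putative permease gene, at 0.956, PDC6, a minor pyruvate decarboxylase gene, at 0.858 and the sulfatase gene BDS1 at 0.808. STR3, the cystathionine beta-lyase gene, was at 0.857, the only one of 6 measured cysteine and glutathione genes in a tail.

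The later steps of methionine synthesis did not stand out in this strain. None of the 12 genes from aspartate and homocysteine to S-adenosylmethionine was in either tail, and their median was 0.0445, at percentile 94.1 of the random lists. The largest values there were SAM1 at 0.126, HOM3 at 0.079, MET17 at 0.076 and MET12 at -0.071. The 7 lists of other amino acid and purine pathways held 0 genes in either tail, and none of their medians was apart from random lists.

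Phosphate genes were also high on the met28 array. Of 11 measured genes of the phosphate regulon, 6 were in the highest 2.5%, and the median of 0.358 was above all 10000 random lists. PHO84, the high-affinity phosphate transporter gene, was at 1.016, SPL2 at 0.984, the acid phosphatase gene PHO5 at 0.519 and PHO12 at 0.451. PHO11 and PHO12 are near-identical, and the array cannot be assumed to tell them apart. Ribosome biogenesis genes had a median of -0.101, below all 10000 random lists, with NOP16 (-0.310), CBF5 (-0.253) and EBP2 (-0.212) in the lowest 2.5% among 28 measured. Ribosomal protein genes had a median of -0.015, at percentile 1.74, which was not apart over genes measured on all 4 arrays (-0.0135), and the general stress list a median of 0.051, at percentile 99.4, with GAC1 at 0.624 as its only tail member. The thiamine, iron and glycolysis lists were apart at medians of 0.086, 0.061 and 0.048, and with the mean in place of the median thiamine (0.0425) and glycolysis (0.0404) were not. Tail members of the thiamine and iron lists were THI22 at -0.270 and the siderophore transporter gene ARN2 at 0.287, and no glycolysis gene was in a tail. Among the 10 highest named genes, 7 belonged to the sulfur lists, and the others were PHO84, SPL2 and ARP10 (0.936). Of these 10 highest, 4 were listed at 0 on at least 1 other array: SPL2, JLP1, SEO1 and ARP10, the last on the met31 and cbf1 arrays. The 10 lowest also held MCM16 (-0.969), STE5 (-0.607), RMD6 (-0.489), RRT7 (-0.483), ACF4 (-0.482) and UTP13 (-0.476), which belong to no list. Of the 10 lowest, only STE5 was listed at 0 on another array, cbf1. YAP5, the gene beside MET28, was at -0.307, in the lowest 2.5%.

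In the strain without CBF1 the same split between sulfate assimilation and transport was present. Of 10 measured sulfate genes, 7 were in the lowest 2.5%, with a median of -0.515 below all 10000 random lists. SUL1 was at -1.119, MET16 at -0.711, MET22, a nucleotide phosphatase gene, at -0.676 and SUL2 at -0.644. MET14, the adenylylsulfate kinase gene, and MET3, the ATP sulfurylase gene, were at 0.193 and 0.041, neither in a tail. Of 7 measured transport genes, 4 were in the highest 2.5%, with a median of 0.281, led by MUP1 at 0.929, MMP1 at 0.699, AGP3 at 0.514 and SAM3, the S-adenosylmethionine permease gene, at 0.281. In the cysteine and glutathione list 3 of 7 were in the highest 2.5%, namely STR3 at 0.790, IRC7 at 0.334 and STR2 at 0.213, with a median of 0.146. In the alternative sulfur list 4 of 10 were in the highest 2.5%: OPT1, a glutathione and oligopeptide transporter gene, at 0.869, BDS1 at 0.529, the glutathione degradation gene DUG3 at 0.527 and the methyltransferase gene MHT1 at 0.460. That list's median was 0.0495, at percentile 97.8.

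Beyond sulfate, single genes of methionine, serine and glycine metabolism were at the extremes on the cbf1 array. MET2, which makes O-acetylhomoserine, was at -0.348 and was the only one of 12 methionine genes in a tail, with MET17 at -0.248 outside it. SER3, which encodes the first enzyme of serine synthesis, was at -0.484 and the threonine aldolase gene GLY1 at 0.264. GCV2, a glycine decarboxylase gene, was at -0.354 and ARO3, an aromatic pathway gene, at 0.329. The medians of the 7 other amino acid and purine lists were not apart from random lists. The general stress list had a median of 0.130, above all 10000 random lists, with HSP26 (0.376), PGM2 (0.243), GLC3 (0.242), GSY2 (0.230) and TPS2 (0.224) in the highest 2.5%, the last 4 being genes of glycogen and trehalose metabolism. The ribosomal protein list had a median of -0.0735, at percentile 0.025, with 115 of its 136 genes below 0 and 0 in either tail. Ribosome biogenesis had a median of -0.084, at percentile 2.17, also with 0 in either tail. The iron list was apart at 0.041, at percentile 98.0, with ARN2 at 0.286. The phosphate list was not apart, with PHO84 at -0.184 and VTC3 at 0.246.

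Among the 10 highest named genes on the cbf1 array, 8 belonged to the sulfur lists, and the others were the nitrilase gene NIT1 (0.439) and the glutaredoxin gene GRX8 (0.434). The 10 lowest held SUL1, CBF1, MET16 and MET22 and 6 genes of no list, namely TVP23 (-1.153), SPO71 (-1.088), SAS2 (-0.817), FMP23 (-0.725), PDR3 (-0.724) and NPP2 (-0.669). Of the 10 lowest, 5 were listed at 0 on another array, among them TVP23, SPO71 and SAS2. Values on this array were more often below 0 (62.9%) than on the others, with a median of -0.034. Read as log10 ratios, 37 genes were at least 2-fold higher and 119 at least 2-fold lower, and after median centring 54 and 73.

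In the strain without MET31, the transport list was low by its median, and the sulfate genes were not apart. Of 7 measured transport genes, 4 were in the lowest 2.5%, with a median of -0.142 below all 10000 random lists. MUP1 was the lowest named gene of the array, at -0.684, followed by SAM3 at -0.324, with MMP1 at -0.146 and MUP3, a second methionine permease gene, at -0.142. The other measured members were in neither tail, with AGP3 at 0.106 and YCT1 at 0.104 above 0 and AGP1 at -0.019. The 9 measured sulfate genes were all outside the tails, with a median of -0.027 at percentile 10.6 and values from -0.080 (MET1) to 0.124 (SUL1). STR3 was at -0.185, in the lowest 2.5%, and SEO1 at 0.362, in the highest. The methionine synthesis list had a median of 0.0080 and no tail member, with MET17 at -0.115 and MET7 at 0.078. The 7 other amino acid and purine lists had no tail member.

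Ribosome biogenesis genes were high on the met31 array, with a median of 0.088 above all 10000 random lists and 27 of 30 above 0. NOP56 was at 0.187, and EBP2, RRP5 and UTP4 were each at 0.166, in the highest 2.5%. The general stress list had a median of -0.0515, above 1 of the 10000 random lists, with 21 of 24 below 0. GAC1 (-0.207), the trehalose synthase subunit gene TSL1 (-0.160), ALD3 (-0.158) and the catalase gene CTT1 (-0.128) were in the lowest 2.5%. Ribosomal protein genes had a median of 0.012, at percentile 99.4, and their mean of 0.0069 was not apart. Among phosphate genes PHM6 was at 0.334 and PHO84 at 0.243, both in the highest 2.5%, and the list's median of -0.012 was not apart. The 10 highest named genes were RNH1 (1.090), RRN9 (0.714), STO1 (0.697), NGL3 (0.538), BDP1 (0.504), SAS10 (0.406), GNT1 (0.402), REX4 (0.394), TMS1 (0.388) and SEO1. RRN9 and BDP1 encode factors of RNA polymerase I and III transcription. Of these 10 genes, 8 were listed at 0 on at least 1 other array. The 10 lowest also held NFT1 (-0.317), TMA10 (-0.299), SOR1 (-0.277), JSN1 (-0.272), PDS1 (-0.268), LAG2 (-0.266) and SPO23 (-0.255). Of the 10 lowest, 4 were listed at 0 on at least 1 other array.

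On the array labelled met32, no sulfur list was apart from random lists. The sulfate list had a median of 0.025, with MET10 (0.180) as its only tail member, and the transport list a median of 0.0105 with none. BDS1 was at -0.242 in the lowest 2.5%, JLP1 at 0.150 and STR3 at 0.164 in the highest. CBF1 was at 0.154, in the highest 2.5%. SER1 (0.187) and SHM1 (0.167) of serine and glycine metabolism were in the highest 2.5%, and the other amino acid and purine lists had no tail member. The general stress and thiamine lists were apart, at -0.043 and -0.044, or 0.043 and 0.044 with the sign turned. The stress list was not apart by its mean (-0.0348), over genes measured on all 4 arrays (-0.017) or with zeros counted as values (-0.017). HSP78 (0.155) and SOL4 (-0.174) were the tail members of the stress list, and THI11 (-0.285), one of a family of near-identical genes, that of the thiamine list. As deposited, the 10 highest named genes were HXT15 (1.3), ATG14 (0.578), GLC8 (0.410), ALG7 (0.384), CSM1 (0.362), COG6 (0.290), GCD6 (0.279), POB3 (0.260), ATE1 (0.253) and ENV11 (0.250). The 10 lowest were PAU19 (-1.058), VMA2 (-0.557), MAL11 (-0.542), MED6 (-0.526), RHO4 (-0.525), YRF1-5 (-0.494), RPR2 (-0.487), OAC1 (-0.462), OPY1 (-0.457) and YRF1-2 (-0.400). HXT15, PAU19, MAL11 and the YRF1 genes belong to families of similar sequence. VMA2 (YBR127C), ATG14 (YBR128C) and OPY1 (YBR129C) are neighbours on chromosome II, where 213 of 422 ORFs were listed at 0 on this array. HXT15 and GLC8 were listed at 0 on the other 3 arrays. Of the 10 highest genes, 4 were at 0 on at least 1 other array, and of the 10 lowest 2. With the sign turned, the highest and lowest genes of this array would change places.

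**Figure D1:**
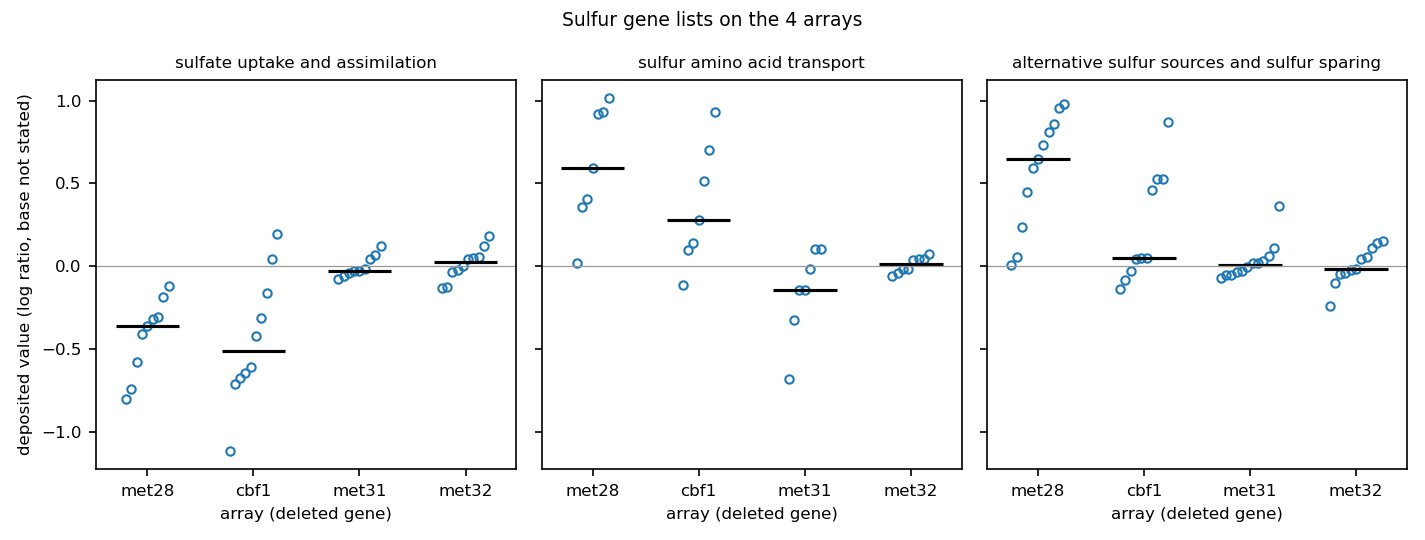
Deposited values (y axis, log ratio of unstated base) of the measured members of 3 sulfur gene lists on each of the 4 arrays (x axis). Each circle is 1 gene and each bar the list median, which for sulfate uptake and assimilation is -0.362 on met28 and -0.515 on cbf1, and for transport 0.591 on met28, 0.281 on cbf1 and -0.142 on met31.

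**Figure D2:**
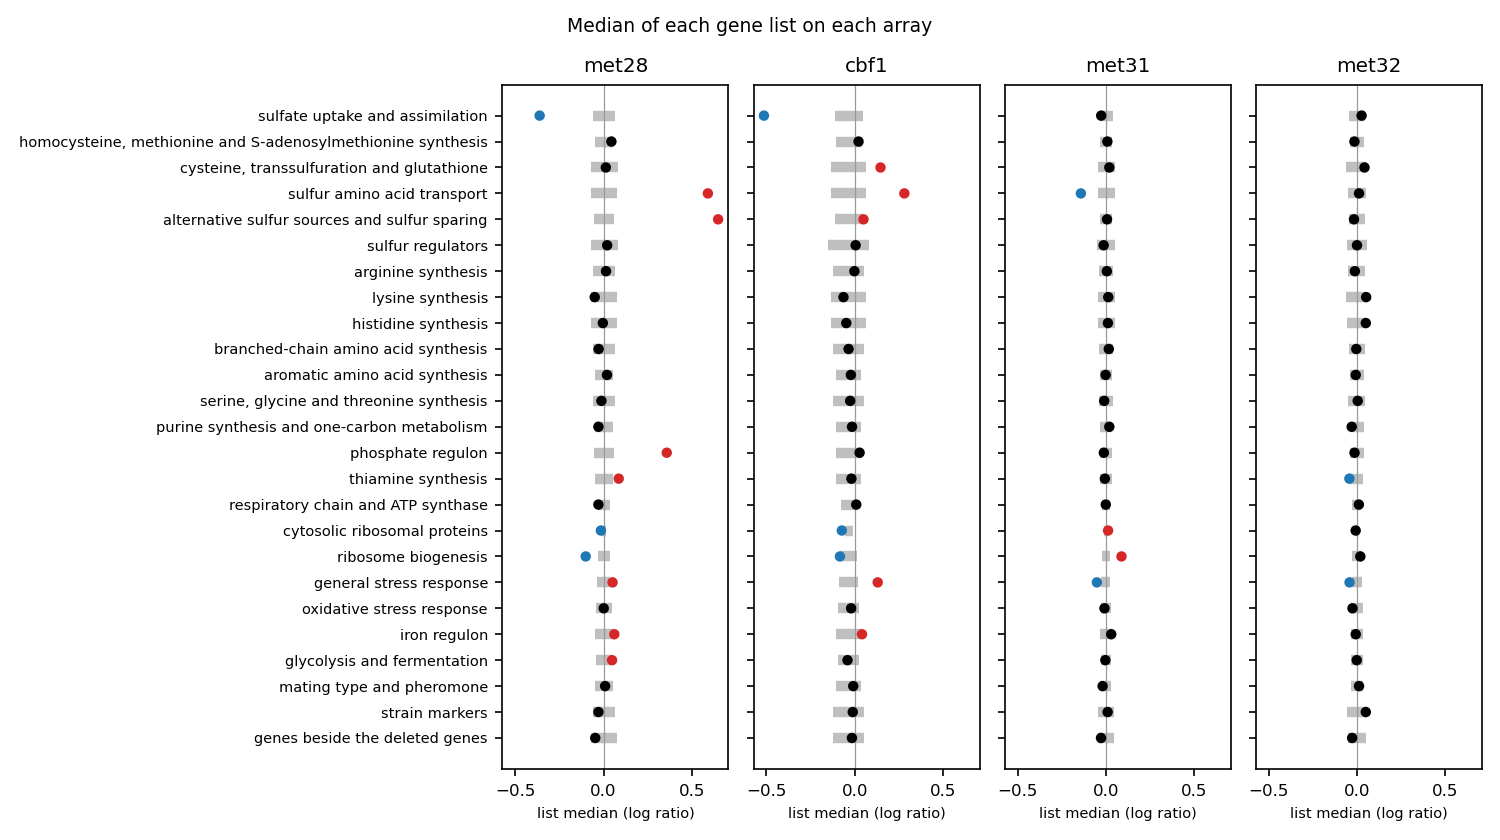
Median of each of the 25 gene lists (y axis) on each array in log ratio units (x axis). Grey bars give the central 95% of medians of 10000 random lists of the same size, and red and blue points lie above and below it, which holds for 10 lists on met28, 8 on cbf1, 4 on met31 and 2 on met32.

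Across the 4 arrays, 24 of 100 list medians were apart from random lists, against 5 expected by chance for lists of independent genes. Genes of a pathway can vary together for other reasons, so the excess does not measure effects of the deletions. The counts were 10 on met28, 8 on cbf1, 4 on met31 and 2 on met32. Of the remaining lists, the oxidative stress, mating type, respiratory chain, strain marker, and neighbouring gene lists were apart on no array. Among single members of these lists, RIP1 of the respiratory chain was at 0.329 on cbf1, ATP4 at 0.287 on met31, ASG7 of the mating type list at 0.396 on met28, and the oxidative stress gene CCP1 at -0.206 on met32. The marker genes URA3, LEU2 and HIS3 lay between -0.136 and 0.108 on the 4 arrays, and MET17, which is also a marker, between -0.248 and 0.076.

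The met28 and cbf1 arrays, which carry the same reference label, shared 18 genes in their highest and 14 in their lowest 2.5%, against 2.43 and 2.63 for independent lists. Of these 32 genes, 16 were members of the sulfur lists. Another 6 genes lay in opposite tails, against 5.07. Over the 49 sulfur genes measured on both, Pearson's r was 0.674 and Spearman's rho 0.619. Over all 5032 genes they were 0.183 and 0.118, and without the sulfur genes 0.103 and 0.110. Genes are not independent replicates. For unchanged strains set against 1 common wild-type RNA, the simulation gave a mean r of 0.50, a covariance of 0.0072 and 45.2 shared tail genes. The observed covariance was 0.0026. The simulation gave wild-type and strain RNA equal spread, so an r near 0.50 and the matching covariance were built in and are no upper limit. Part of the overlap may therefore come from a shared reference. The largest differences between these arrays were PHO84 (1.016 on met28 and -0.184 on cbf1), SEO1 (0.956 and -0.027), HXT12 (0.632 and -0.322) and PDC6 (0.858 and -0.082), besides the deleted genes. In the other direction they were MCM16 (-0.969 and 0.047), PET117 (-0.171 and 0.339), ATR2 (-0.254 and 0.226) and IES6 (-0.222 and 0.255).

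The met31 and met32 arrays shared 7 tail genes in the same direction, against 7.01 for independent lists, and 10 in opposite directions, against 7.02. The shared genes were YOR200W, CDC60, ATP4, CRC1, MRE11 and POB3 on the high side and YBR209W on the low side, none of them in the sulfur lists. Over the 51 sulfur genes measured on both, r was -0.011 and rho -0.097, or 0.011 and 0.097 with the met32 sign turned. Over all 5528 genes r was 0.113 and rho 0.155, or -0.113 and -0.155 with the met32 sign turned, against r = 0.50 and 50.2 shared tail genes in the simulation with a common wild-type RNA. The covariance was 0.00065 against 0.0029 simulated. As for met28 and cbf1, the simulated r and covariance were built in by the equal spread, so they do not test for a common wild-type RNA. In the deposited direction MUP1 differed most among genes higher on met32, at -0.684 on met31 and -0.042 on met32, followed by ATG14 (-0.002 and 0.578), SOR1 (-0.277 and 0.202), ALG7 (-0.062 and 0.384) and ROY1 (-0.244 and 0.189). RNH1 (1.090 and -0.048), PAU19 (-0.052 and -1.058), STO1 (0.697 and -0.103), RRN9 (0.714 and 0.095) and RHO4 (0.018 and -0.525) were higher on met31. With the met32 sign turned, PAU19 (-0.052 and 1.058) led the genes higher on met32, ahead of MUP1 (-0.684 and 0.042), and RNH1 (1.090 and 0.048) still led those higher on met31. Pairs with different reference labels had r of -0.129 for met28 and met31, -0.040 for met28 and met32, 0.109 for met31 and cbf1, and 0.063 for met32 and cbf1, making 6 correlations in all. With the met32 sign turned, those with met28 and cbf1 were 0.040 and -0.063.

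**Figure D3:**
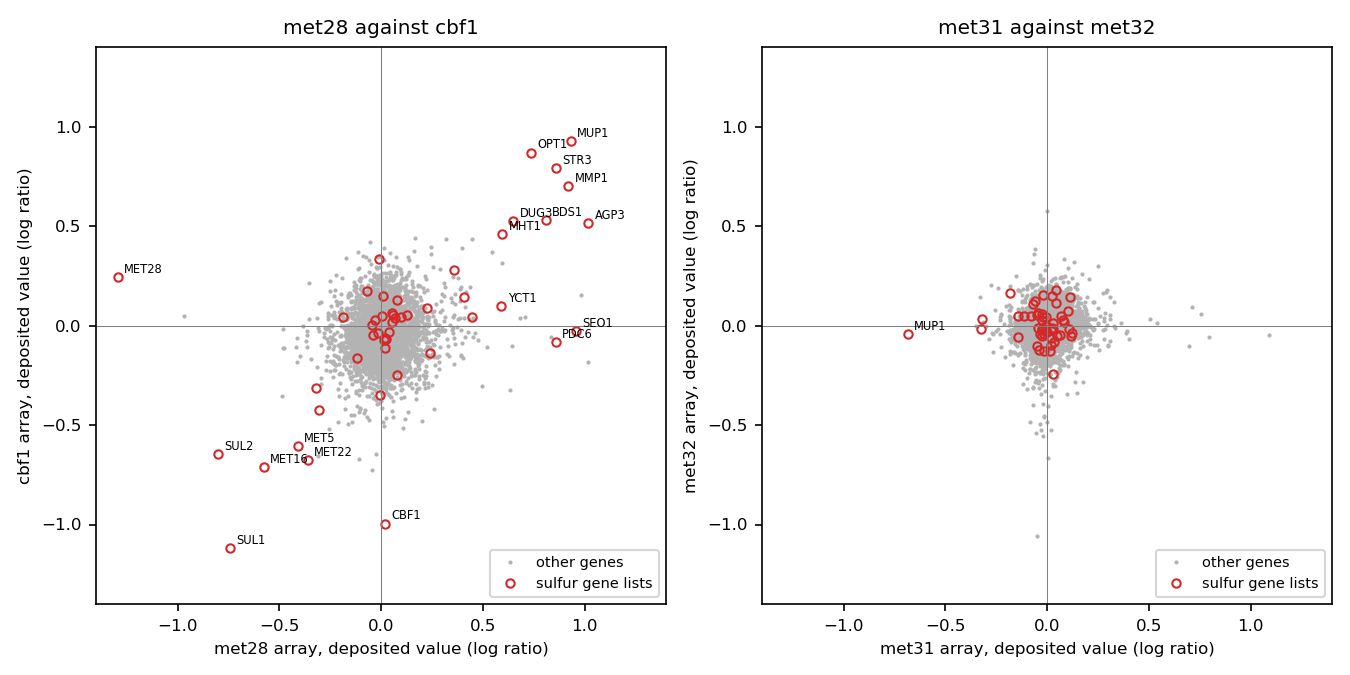
Deposited values per gene on the met28 array against the cbf1 array (left) and on the met31 array against the met32 array (right), in log ratio units. Red circles are genes of the sulfur lists, which have r = 0.674 on the left and -0.011 on the right (0.011 with the met32 sign turned), and grey points are the other genes measured on both arrays.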

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

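The tests in this part were chosen after the results were seen, apart from the test of a common wild-type RNA for the sulfate and transport lists. Results below were picked out because a list's median lay outside the random range in opposite directions on 2 arrays. With 1 array per strain the differences themselves were not tested across replicates, and all of these pairs have different reference labels. The sulfur amino acid transport list was higher on met28 than on met31 by a median of 0.681 (7 of 7 genes), and met31 minus cbf1 was -0.408 (5 of 7 genes higher on cbf1). Ribosome biogenesis differed by -0.181 for met28 minus met31 (26 of 28 genes higher on met31) and by 0.170 for met31 minus cbf1 (27 of 29). Ribosomal protein genes differed by -0.0285 and 0.081 in the same comparisons. Their list was not apart on met28 over genes measured on all 4 arrays (-0.0135) nor on met31 by its mean (0.0069). All differences with cbf1 here include the offset of its array median (-0.034, against -0.002 on met31 and met32). For ribosomal protein genes the random range of met31 minus cbf1 was 0.013 to 0.059. The general stress list differed by 0.097 for met28 minus met31, -0.167 for met31 minus cbf1, 0.093 for met28 minus met32 and -0.129 for met32 minus cbf1. With the met32 sign turned the last 2 values were 0.009, inside the random range, and -0.091. The stress list on met32 was itself not apart by its mean (-0.0348), over genes measured on all 4 arrays (-0.017) or with zeros counted as values (-0.017). The thiamine list differed by 0.126 for met28 minus met32, and by -0.032, inside the random range, with the met32 sign turned. By its mean the list was not apart on met28 (0.0425).

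On the met28 and cbf1 arrays the sulfate list was low and the transport list high. The gap between their medians was at least 0.796, but how methionine alone moves either list was not measured here, so a difference in methionine between the channels stays open. Of the 16 genes of these lists measured on both arrays, 14 (87.5%, Wilson limits 63.98% to 96.5%) lay on the same side of the array medians. Random error of single spots, independent between the arrays, would give 50% in lists not picked for their values. The lists were fixed before the data were examined, but these 2 were picked after, because each lay in the same direction on both arrays. That choice favours a high share, so the share cannot test random error. An error of poorly measured spots that repeats on both arrays stays open. Of the 13 genes of these lists in a tail, 0% were listed at 0 on met31 or met32, compared with 11.3% of all 495 tail genes of met28 and cbf1. The upper Wilson limit of 22.8% (counting error only) includes that share. Besides, 82.8% of the met32 zeros lay on chromosomes I and II, so a 0 on met32 need not mark a poor spot. A common wild-type RNA cannot be told apart from a shared effect of the deletions, since met28 minus cbf1 was 0.114 for the sulfate list, inside the random range, and 0.220 for the transport list, outside it. The alternative sulfur list was higher on met28 than on cbf1 by a median of 0.207, outside the random range of -0.053 to 0.132. Of its 10 genes measured on both, 8 were higher on met28 and 2 on cbf1. The list was picked for its high median on met28, which favours such a difference. These values therefore do not settle whether a common wild-type RNA was the whole cause there. An effect of the deletions themselves stays open and was not tested. Arrays of both strains and of wild type, each with and without methionine, would separate it from methionine supply, provided that the deletion strains grow without methionine.

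Ribosome biogenesis and general stress genes lay on opposite sides of the array median on 4 of 4 arrays, counting signs only. Both lists were apart from random lists on 3 of them, and on met32 the ribosome biogenesis median of 0.018 (percentile 92.6) was not. On cbf1 the ribosome biogenesis call was narrow, with a median of -0.084 against a random limit of -0.083 (percentile 2.17). Opposite sides would follow from a difference in growth state between the 2 cultures of a hybridisation, a hypothesis found on these values. On met28 and met31, 41 of 51 genes of these lists (80.4%, limits 67.5% to 89.0%) lay on opposite sides. The lists were picked because their medians lay in opposite directions on these arrays. That choice favours a high share, so the share cannot test random error of single spots. An error of poorly measured spots that moves a whole list stays open, since the genes measured on all 4 arrays are the same 28 as before, and the ribosome biogenesis difference between met28 and met31 of -0.181 could not move. The tables argue against a turned ratio on the met31 array, where MET31 was at -0.320 in the lowest 2.5%. Whether the deletions or the cultures' stage of growth set this difference was not tested.

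The met32 array stood apart in its missing values and in its own deleted gene. Chromosomes I and II held 82.8% of its zeros, with 100 of 104 ORFs of chromosome I and 213 of 422 of chromosome II at 0, compared with 6.27% to 6.58% of the zeros on the other arrays. A stretch of the column without values is a candidate explanation for that part. Rows of the whole column out of register are argued against by a rank correlation with the met31 array of 0.155 in register, compared with -0.049 to 0.033 at offsets of up to 100 rows. An intact MET32 gene in the strain used stays open, since MET32 was at 0.012 there and varied little on any array (-0.066 to 0.027), which a weak probe would give as well.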

How the results depend on the processing

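No paired analysis was possible because each strain has 1 column and the labels give no replicate numbers, and leaving out a replicate was not possible either. The log base decides how many genes pass a fold threshold. The tails held 264 genes on met28, 298 on met31, 300 on met32 and 269 on cbf1. Read as log10, 137, 28, 34 and 156 genes passed 2-fold (after the data were seen), 46, 8, 11 and 31 passed 3-fold, and 467, 149, 203 and 793 passed 1.5-fold. With median centring the 2-fold counts were 137, 30, 33 and 127, and with all arrays set to a common robust SD 127, 85, 61 and 38. On cbf1, 23.7% of the genes past 2-fold were higher, 42.5% after centring and 34.2% after setting the SD. Read as log2 (added later), 4, 1, 2 and 3 genes passed 2-fold, and as natural logarithms (added later) 22, 5, 2 and 12. The genes past the threshold in the same direction on met28 and cbf1 were 32 in the tails, 72 at 1.5-fold, 22 at 2-fold and 10 at 3-fold if log10, against 5.05, 25.5, 1.15 and 0.061 for independent lists. For met31 and met32 they were 7, 3, 0 and 0, against 7.01, 2.17, 0.050 and 0.0029, all in the deposited direction. With the met32 sign turned the tails shared 10, and the fold counts were not analysed with the sign turned. Both overlaps stayed at 32 and 7 without the deleted genes, their neighbours and strain markers. The search of promoters for motifs was not run.

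Centring shifts every gene of an array alike, so it cannot move a list's place among random lists or the genes in the tails, and it tests neither. For the 40 medians of the sulfur, phosphate, ribosome and stress lists, leaving out the deleted genes, their neighbours and strain markers changed none of the 37 calls it could be run for, which lack the sulfur regulators on met28, met31 and cbf1. The mean in place of the median put apart the cysteine list on met28 (0.180) and the sulfur regulators on met28 (-0.101), met31 (-0.0555) and cbf1 (-0.154), the last 3 of which include the deleted gene. It ended the calls of ribosomal proteins on met31 (0.0069) and general stress on met32 (-0.0348). Over genes measured on all 4 arrays, ribosomal proteins on met28 (-0.0135) and general stress on met32 (-0.017) were no longer apart, and the cysteine list on met32 was (0.065). With zeros counted as values (added later), general stress on met32 (-0.017) was not apart, and methionine synthesis on met28 was (0.0445). Among the other 60 medians, the mean ended the calls of thiamine (0.0425) and glycolysis (0.0404) on met28 and put apart oxidative stress on met32 (-0.045). Genes measured on all 4 arrays put apart the respiratory chain on cbf1 (0.017) and mating type on met31 (-0.040), and zeros counted as values the respiratory chain on met28 (-0.020) and cbf1 (0.006). For these list calls the cause was not tested. Under these alternatives no list that was apart from random lists was apart in the opposite direction, though some medians near 0 changed sign. Turning the met32 sign reverses both calls on that array. Without RPP1, a gene of RNase P that the symbol rule takes into the ribosomal protein list, its medians were -0.0145, 0.0115, -0.008 and -0.075 on met28, met31, met32 and cbf1, with no call changed (added later). Signal over background is unknown, so weak spots could not be left out.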

Other observations

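The values in this part were picked after the data were seen. Some of the highest values on the met28 array came from genes that lie side by side. Among 5392 runs of 8 neighbouring protein-coding genes, the largest median was 0.597, for the run from BDS1 (YOL164W) to IMA2 (YOL157C), which also holds YOL163W (0.825) and YOL162W (1.039). The next was 0.591, for the run from MHT1 to YLL054C on another chromosome, which holds MHT1, MMP1, HSU1, JLP1 and YCT1. On the met31, met32 and cbf1 arrays the most extreme runs had medians of 0.107, -0.127 and -0.234. The neighbours STE5 (YDR103W), SPO71 (YDR104C), TMS1 (YDR105C) and ARP10 (YDR106W) were extremes on different arrays. STE5 was at -0.607 and ARP10 at 0.936 on met28, SPO71 at -1.088 on cbf1 and TMS1 at 0.388 on met31. Each was listed at 0 on at least 1 other array, and the cause was not tested.

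Outside the sulfur lists, the met28 and cbf1 arrays shared ADI1, a methionine salvage gene (0.547 and 0.371), the methionine sulfoxide reductase gene MXR1 (0.397 and 0.388), GRX8 (0.444 and 0.434), LEE1 (0.593 and 0.314) and TMA10 (0.317 and 0.433) in their highest 2.5%. TMA10 was at -0.299 on the met31 array. In the lowest 2.5% they shared TRI1 (-0.309 and -0.654), RMD6 (-0.489 and -0.353) and KIN82 (-0.255 and -0.519).

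The 7 YRF1 genes, which encode near-identical helicases of subtelomeric Y' elements, were looked at because YRF1-5 and YRF1-2 were among the 10 lowest genes on the met32 array. Their median there was -0.312 as deposited, with 7 of 7 below 0, and the direction of that array is not settled. With such similar sequences they count as about 1 measurement, and having been picked for their values they test nothing. Their medians were 0.042, -0.041 and 0.017 on the met28, met31 and cbf1 arrays.

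Genes in the tails were more often listed at 0 on another array than other measured genes on met28 (28.4% of 264 against 10.2% of 4978) and on met31 (44.3% of 298 against 19.7% of 5595). The Wilson 95% limits were 23.3% to 34.1% against 9.36% to 11.0%, and 38.8% to 49.97% against 18.6% to 20.7%. On met32 the shares were 22.3% and 20.7%, and on cbf1 15.6% and 13.3%, with overlapping limits. Zeros were shared between met28 and cbf1, which carry the same reference label, for 667 ORFs against 143 expected if independent. They were also shared between arrays with different reference labels, for 292 against 51.4 between met31 and cbf1 and for 278 against 59.7 between met28 and met31. With met32 the numbers were 46 against 61.5 for met28, 13 against 22.2 for met31 and 41 against 53.0 for cbf1. The met32 zeros, 82.8% of them on chromosomes I and II, also enter the shares above for the other arrays.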
